A study of Mus musculus with 3 samples.

How the data were processed

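The study measured cytosolic RNA of C57BL/6J bone-marrow-derived macrophages in 3 libraries of one group, labelled replicates 1, 2 and 3. Per the labels, 1 µg of RNA entered each library and inserts were 250 to 400 bases long. The labels call the libraries biological replicates and give all of them one donor identifier. P-values of tests between libraries therefore measure only the spread between these libraries, and whether separate animals gave them is not stated. P-values against random lists or over genes measure the spread between genes. Nothing links the libraries to other groups, so no contrast between conditions was made.

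Each library had 3 deposited tables. The authors deposited expected counts per gene and per transcript, made from a transcriptome alignment to mm10 with GENCODE M21, per the notes that accompany the files. These are estimates that need not be whole, and their column names are those RSEM writes. The authors also deposited TPM in the same tables, named so per the file headers, which scales each library to a fixed total over all listed features, spike-in and tRNA entries included. The deposited share of each transcript in its gene is a percent of the gene's TPM. A further transcript table was made directly from the reads, and its deposited estimated counts and TPM have the column names kallisto writes. Tool versions, strand setting and filters are not given in the sources used here. FPKM columns were not used here.

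Gene symbols, classes and coordinates come from the GENCODE annotation of the same release on mm10, in which all 55536 gene identifiers were found. Entries for spike-ins and tRNAs name no gene and stayed out of the gene tests. They comprised 96 ERCC entries with 0 counts in every library, 26248 tRNA entries with 5, 0 and 0 counts in replicates 1, 2 and 3, and the phiX control. Totals were 32108408, 53165872 and 57117456 expected counts. A named gene with 0 counts in every library is given with the level, for a group of genes the highest of them, that 3 counts would make, the highest over the libraries at 0, which covers counting error only.

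Gene lists, named-gene rules, tests and most alternatives were fixed before the data were examined. The lists cover macrophage identity, TLR4 signalling, NF-kB subunits and inhibitors, immediate early genes, inflammatory cytokines and mediators, feedback inhibitors, antimicrobial and pattern recognition effectors, interferon-stimulated genes, alternative activation, AU-rich element binding proteins and RNA decay. They also cover nuclear-retained RNAs, cytosolic noncoding RNAs, mitochondrially encoded mRNAs, replication-dependent histones, cytosolic ribosomal proteins, cell cycle, glycolysis and housekeeping genes, and markers of 7 other cell types. Named genes are the 10 highest nuclear-encoded protein-coding genes outside the ribosomal proteins, the 4 highest and 2 lowest members of each list (every member in lists of 6 or fewer), and the 10 highest of the TLR4, NF-kB, cytokine, feedback and immediate early lists. Any other member of these 5 lists may be named under the rule, and Il6, Cxcl1, Nos2, Ifnb1, Ier2, Egr1 and Nr4a1 were picked in this way after their values were seen. The rule adds the 10 largest BCVs among genes with a mean of at least 100 counts, the 10 highest noncoding genes and the leading transcripts of 18 genes. Firre, Airn, Pvt1, Tsix, Marco, the Y-linked genes and the pseudogenes Gm12895 and Gm12896 lie outside this rule and were chosen after their values were seen. Some genes that the rule would name are not reported here. Where a symbol named several genes, the entry with the higher mean TPM was taken.

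The level of a list is the median of log2(mean TPM + 1) over its members, placed among 10000 random lists of the same size from 22028 protein-coding genes, with a two-sided permutation p adjusted by Benjamini-Hochberg over 23 lists. The smallest p such lists can give is 0.0002. The noncoding lists and Mx2 were left out of this test because the background is protein coding, a choice made after the data were seen. Feedback and cytokine genes were compared by a two-sided permutation test over genes with 100000 resamples, and Il10, which is on both lists, was left out. Detection required 1 TPM in every library. Nuclear-encoded protein-coding genes took 34.3%, 27.8% and 27.8% of TPM in replicates 1, 2 and 3, so libraries were compared on log2 CPM.

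Expected counts were rounded to whole numbers for edgeR 4.0.16 in R 4.3.3, with its expression filter, TMM normalization and an intercept-only dispersion fit. Genes varying beyond counting error were found by a chi-square test per gene against a single rate. The spread of a list is its median tagwise BCV among 10000 random lists matched on deciles of mean expression. The departure of a library is the median over a list of log2 CPM, counts scaled to library size (prior count 2), minus the mean of the other libraries, placed among matched random lists without a p-value. Lists with fewer than 3 tested members were left out, which leaves 20 lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used for the rest.

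The steps were tested on simulated data. With counts drawn at the real means and depths and a BCV of 0.1, a simulated 2-fold rise of 25 genes in replicate 1 was recovered by the departure step over 13435 genes as a median log2 difference of 0.96, and a 1.5-fold rise as 0.55. Of 200 unchanged lists of 20 genes, 2% had a two-sided permutation p under 0.05 in the departure step, a p not given for the real lists, 4% in the spread step, and of 200 random lists 3% in the level step over 22028 genes. Of the genes simulated with a BCV of 0.6, 68% were among the same number of highest BCVs. With counting error alone, 0 of 13493 genes were called as varying by the chi-square test. In the simulated counts genes varied independently, and most had a BCV of 0.1, against a common BCV of 0.235 in the real data. The simulated rates therefore do not cover lists whose members move together.

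Alternatives were another pseudocount, expressed genes only, the quantification made from reads, TPM rescaled to nuclear-encoded protein-coding genes, other detection minima, TPM in place of count shares, DESeq2 1.42.0 size factors, no expression filter, the SD of log2 TPM in place of BCV, matching on gene length as well, and each replicate left out. The departures on protein-coding genes or protein-coding transcripts alone, and the list spread without each replicate, were chosen after seeing the data.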

Results

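The data describe primary macrophages grown from the bone marrow of C57BL/6J mice. The cells received 100 ng/ml Lipid A, the part of bacterial endotoxin that Toll-like receptor 4 recognises, for 12 h. After a washout of 12 h they received 100 ng/ml Lipid A again for 10 min. RNA of the cytosolic fraction was depleted of ribosomal RNA and sequenced. The 3 libraries were labelled as biological replicates 1, 2 and 3 of this single condition, and all carry the same donor identifier. No untreated, singly treated or nuclear library was analysed here, so the values are levels in restimulated cells and not responses to the treatment. The libraries held 32108408, 53165872 and 57117456 expected counts. Values are TPM, a transcript abundance scaled to a fixed total per library, given as mean ± SD over the libraries (n = 3) unless a library is named.

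Genes of iron storage, a chemokine and an acute-phase protein were the most abundant protein-coding genes. Fth1 and Ftl1, which encode the ferritin chains, stood at 17787 ± 1494.6 and 7782 ± 727 TPM (n = 3). The chemokine Ccl5 and the acute-phase protein gene Saa3 followed at 4987 ± 1671 and 4622 ± 2239 TPM, then Tmsb4x at 4583 ± 831 and Psap at 3882 ± 411 TPM. B2m (3772 ± 762), Actb (3462 ± 704), lysozyme gene Lyz2 (2989 ± 197) and the lysosomal protease gene Ctsd (2889.9 ± 162) completed the 10 highest outside the ribosomal protein genes. Counts of Fth1, Ftl1, Actb, Lyz2 and Ctsd were fractional, which marks reads shared with other annotated copies or loci, so these levels carry that uncertainty. All 20 macrophage identity genes reached 10 TPM, with Mrc1 lowest at 20.6 ± 4.40 TPM. Lyz2 and Ctsd led this list, followed by Ctsb at 2295 ± 279 and Apoe at 1129 ± 196 TPM. A total of 9583 genes reached 1 TPM in every library, of which 9122 were protein coding and 186 long noncoding. At a minimum of 5 TPM the total was 5961, and with at least 10 expected counts it was 12387. Nuclear-encoded protein-coding genes took only 29.9% of TPM. Cutoffs of 1 or 10 TPM are therefore stricter for them than where they fill most of the TPM. A gene under 1 TPM need not be absent.

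Markers of other cell types were scarce. Of 10 lymphocyte markers 8 lay under 1 TPM, with Cd4 at 17.2 ± 3.67 and Cd79b at 1.86 ± 0.395 TPM the exceptions. Among 10 neutrophil and granulocyte precursor markers 7 lay under 1 TPM, while Csf3r stood at 35.9 ± 12.1, S100a9 at 5.45 ± 1.21 and S100a8 at 3.04 ± 1.01 TPM. All 7 erythroid, 7 dendritic cell, 7 fibroblast and stroma, and 5 mast cell and basophil markers were under 1 TPM. Their highest members were Alas2 (0.173 ± 0.240), Ccr7 (0.997 ± 0.251), Pdgfrb (0.0233 ± 0.0115) and Prss34 (0.0733 ± 0.0321). Of 5 megakaryocyte markers, Pf4 reached 83.1 ± 4.71 TPM and Ppbp, Itga2b, Gp9 and Gp1bb did not reach 1 TPM. Macrophages are known to express Csf3r, Cd4 and Pf4 too. Cd3e, Nkg7, Ly6g, Retnlg, Hbb-bs, Cd209a, Gp9 and Gp1bb had 0 counts in every library, which allows up to 0.382 TPM for the least certain of them, Hbb-bs (3 counts, counting error only). None of the 7 marker lists stood apart from random protein-coding lists, with adjusted permutation p from 0.576 to 0.921. This test could hardly call a silent list lower, because random lists hold many silent genes too. The fibroblast and stroma list, with a median of 0.0133 TPM, still lay at percentile 30.1. The scarcity of these markers therefore rests on their levels and not on this test.

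The Lipid A receptor and its signalling genes were expressed at moderate levels. Tlr4 (ENSMUSG00000039005.13, chromosome 4, 66827584 to 66930284) stood at 26.6 ± 5.43 TPM (n = 3), and its partners Ly96 and Cd14 at 24.6 ± 5.65 and 52.05 ± 9.05 TPM. The adaptor Myd88 reached 48.2 ± 9.70 TPM and the kinase genes Ikbke, Tbk1, Ikbkb, Irak2 and Irak1 63.3 ± 34.5, 27.8 ± 9.73, 20.99 ± 3.16, 16.2 ± 5.93 and 13.9 ± 1.38 TPM. Tab2 stood at 26.7 ± 5.42 TPM. At the low end were Tab3 at 2.94 ± 0.444 and Lbp at 0.667 ± 0.146 TPM, and 14 of the 23 genes reached 10 TPM. The list had a median of 11.3 TPM and lay at percentile 99.99 of random lists of protein-coding genes (adjusted permutation p = 0.00102). Against expressed genes alone it lay at percentile 82.8 (adjusted permutation p = 0.451), so the call holds only where silent genes are in the background.

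Genes of NF-kB, the transcription factor downstream of this receptor, were led by its inhibitor. Nfkbia (ENSMUSG00000021025.8, chromosome 12, 55489410 to 55492647) stood at 66.5 ± 18.5 TPM (n = 3), above the subunit genes Nfkb1 (24.8 ± 5.16), Nfkb2 (20.96 ± 3.39), Rela (17.1 ± 1.29), Relb (10.4 ± 1.56) and Rel (6.63 ± 1.61). Nfkbib, Bcl3, Nfkbiz and Nfkbie had 19.1 ± 1.63, 16.3 ± 5.005, 8.35 ± 3.41 and 7.86 ± 3.25 TPM, and Nfkbid was lowest at 1.27 ± 0.330 TPM. The 11 genes had a median of 16.3 TPM (percentile 99.9, adjusted permutation p = 0.00345). With expressed genes alone as background the percentile was 91.7 (adjusted permutation p = 0.235).

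Inflammatory cytokine and mediator genes spanned the widest range of the signalling lists. Ccl5 (ENSMUSG00000035042.2, chromosome 11, 83525778 to 83530518) at 4987 ± 1671 TPM was followed by Cxcl10 at 429 ± 367, Ccl3 at 201 ± 72.2, Ccl4 at 179 ± 82.4, Ccl7 at 131 ± 56.5 and Ccl2 at 119 ± 49.5 TPM (n = 3). Tnf (ENSMUSG00000024401.14, chromosome 17, 35199381 to 35202007) stood at 61.7 ± 25.4 TPM, Il1a at 12.5 ± 2.69, Il1b at 10.1 ± 4.10 and the anti-inflammatory cytokine Il10 at 7.16 ± 4.73 TPM. Il6 and Cxcl1 stayed at 0.733 ± 0.140 and 0.733 ± 0.212 TPM, and the lowest members, Il12a and Lif, at 0.03 ± 0.01 and 0.01 ± 0 TPM. Of 24 genes 8 lay under 1 TPM. The list, with a median of 3.82 TPM, did not differ from random lists at the adjusted threshold (percentile 97.2, adjusted permutation p = 0.0949).

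Genes that restrain Toll-like receptor signalling were broadly present. Acod1, whose enzyme makes itaconate, stood at 329.8 ± 155 TPM, Trim30a at 114 ± 38.4, the repressor Atf3 at 98.4 ± 27.1 and the phosphatase gene Inpp5d at 50.2 ± 8.67 TPM (n = 3). The interleukin-1 receptor antagonist Il1rn had 48.96 ± 23.6 TPM, the mRNA decay factor Zfp36 47.1 ± 8.13, Tnip1 32.2 ± 4.88, Tnfaip3 22.6 ± 8.95 and Tollip 16.2 ± 2.23 TPM. Sigirr and Cish were lowest at 0.353 ± 0.137 and 0.173 ± 0.0306 TPM. Of 19 genes 17 reached 1 TPM, with a median of 16.2 TPM (percentile 99.98, adjusted permutation p = 0.00138). Compared directly, the 18 feedback genes averaged 4.35 ± 2.15 and the 23 cytokine genes 3.35 ± 3.49 in log2(TPM + 1), SD over genes. The difference of 0.99 was not past the threshold in a two-sided permutation test over genes (p = 0.299). With a pseudocount of 0.1 it was 1.66 (permutation p = 0.165). Among members of at least 1 TPM its direction turned, with feedback minus cytokine at -0.16 (permutation p = 0.865). Genes are not independent replicates in these tests.

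**Figure D1:**
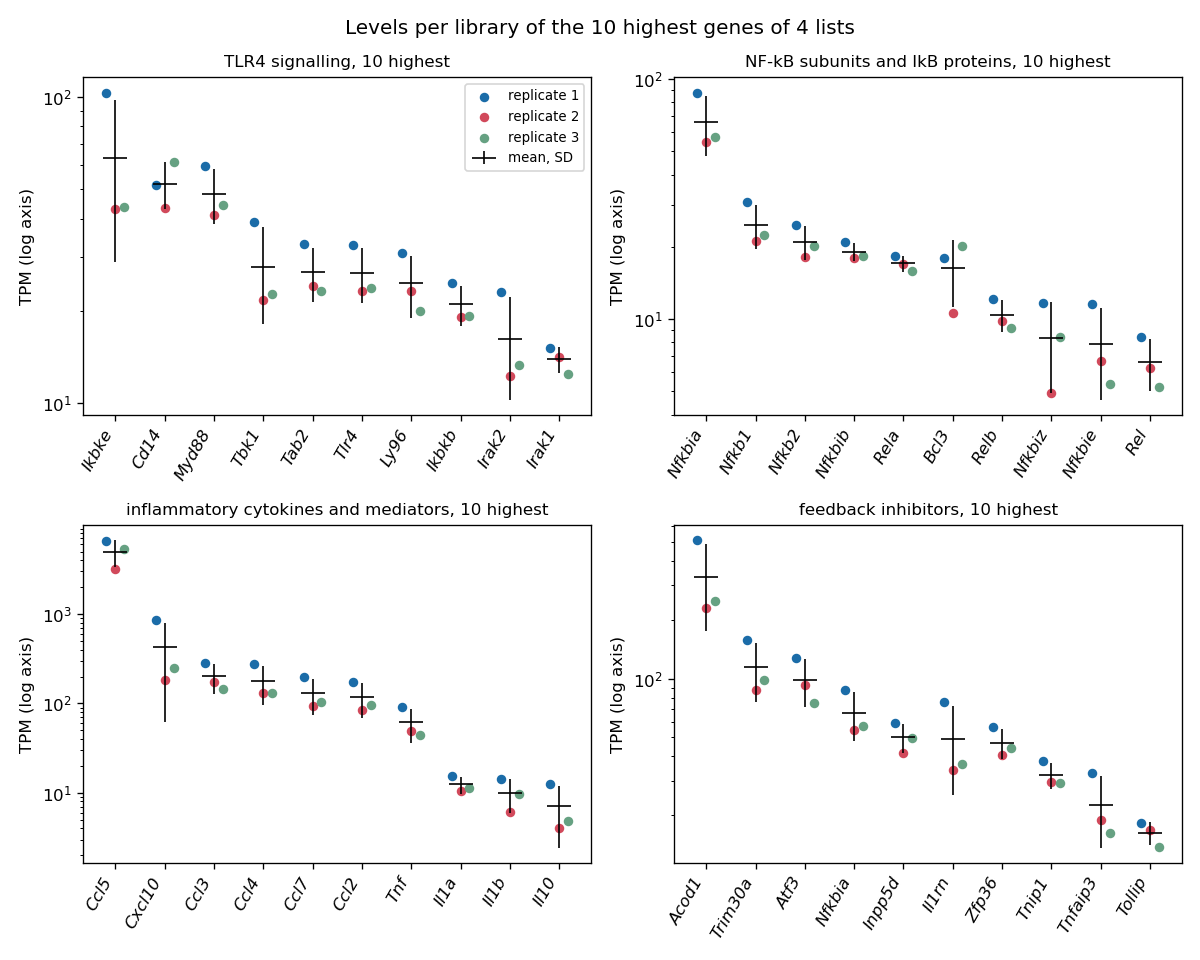
TPM on a log axis for the 10 highest genes of 4 lists, with a point per replicate and a horizontal mark and bar for mean and SD (n = 3). In the cytokine panel, Ccl5 lies highest at 4987 TPM and Cxcl10 ranges from 185 TPM in replicate 2 to 851 TPM in replicate 1.

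Immediate early genes, the first to be transcribed after a stimulus, were unevenly represented 10 min after the second Lipid A dose. Atf3 (98.4 ± 27.1), Klf6 (84.1 ± 28.8), Zfp36 (47.1 ± 8.13), Junb (40.1 ± 7.25), Jund (31.4 ± 4.82) and Jun (28.04 ± 4.30) were the highest, in TPM (n = 3). Ier5, Ier3, Dusp1 and Fos followed at 20.4 ± 1.30, 17.7 ± 2.61, 7.66 ± 1.61 and 5.91 ± 1.79 TPM. Nr4a3 stood at 0.11 ± 0.0436 TPM and Fosl1 had 0 counts in every library, which allows up to 0.0973 TPM. Of 26 genes 10 lay under 1 TPM, and the list, with a median of 3.43 TPM, was not past the threshold (percentile 97.1, adjusted permutation p = 0.0949). Genes on the mixed list of AU-rich element binding proteins and RNA decay reached a median of 17.9 TPM (percentile 99.97, adjusted permutation p = 0.00167). These are RNA levels and do not measure decay activity. Ybx1 led them at 124 ± 13.5 TPM, followed by Zfp36, Hnrnpd at 41.2 ± 4.59 and Zfp36l1 at 39.6 ± 3.80, with Auh (6.75 ± 0.631) and Tia1 (4.14 ± 2.20) lowest. Against expressed genes alone this list was not past the threshold (adjusted permutation p = 0.151).

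Interferon-stimulated genes were expressed throughout the list. All 23 protein-coding members reached 10 TPM, led by the antiviral genes Ifit2 (975 ± 447), Rsad2 (890.0 ± 489), Irf7 (729 ± 255) and Ifit3 (651 ± 223), in TPM (n = 3). Oas2 was the lowest at 20.7 ± 14.02 TPM, below Mx2 at 26.1 ± 18.1 TPM, which the annotation lists as a polymorphic pseudogene and which was left out of the level test. The list had a median of 177 TPM (percentile 100, adjusted permutation p = 0.000575). Antimicrobial and pattern recognition genes had a median of 64.9 TPM (percentile 100, adjusted permutation p = 0.000575). Saa3, Lyz2, Acod1 and the complement gene C3 (94.6 ± 24.1 TPM) led this list, and Camp and Ptx3 were lowest at 0.0767 ± 0.0814 and 0.00333 ± 0.00577 TPM. Genes of alternative activation, the interleukin-4 programme, had a median of 1.76 TPM (percentile 77.6, adjusted permutation p = 0.608). Among them Il4ra stood at 44.1 ± 12.5, Mrc1 at 20.6 ± 4.40, Tgm2 at 14.9 ± 6.42 and Clec10a at 3.003 ± 0.345 TPM, while Retnla was at 0.02 ± 0.0346 TPM and Ccl17 had 0 counts, which allows up to 0.237 TPM.

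Metabolic and structural lists lay above random lists as well. Glycolysis genes had a median of 65.1 TPM (percentile 100, adjusted permutation p = 0.000575), with Gapdh at 355 ± 35.6, Pkm at 161 ± 6.26, Aldoa at 161 ± 3.998 and Hk3 at 122 ± 30.7 TPM, and Pfkl and Slc2a1 lowest at 3.93 ± 0.419 and 2.56 ± 0.379 TPM (n = 3). Cytosolic ribosomal protein genes had a median of 173 TPM (percentile 100, adjusted permutation p = 0.000575), led by Rpl41 at 784 ± 121, Rps24 at 702 ± 97.8, Rps29 at 633 ± 84.5 and Rplp1 at 484 ± 38.5 TPM. Rpl3l and Rpl10l were lowest, at 0.03 ± 0.0436 TPM and 0 counts, which allows up to 0.0831 TPM. Housekeeping genes had a median of 227 TPM (percentile 100, adjusted permutation p = 0.000575), from B2m, Actb, Eef1a1 (906 ± 108) and Ppia (479 ± 23.8) to Hprt (31.5 ± 2.32) and Tbp (4.55 ± 0.930). Mitochondrially encoded mRNAs had a median of 187 TPM (percentile 100, adjusted permutation p = 0.000575), led by mt-Atp8 at 1223 ± 489, mt-Co1 at 1026 ± 411, mt-Nd6 at 227 ± 82.2 and mt-Nd1 at 212 ± 45.9 TPM. The low values of mt-Atp6 (61.5 ± 28.8) and mt-Co2 (6.38 ± 5.58) are uncertain, as are those of mt-Co1. Their fractional counts mark reads shared with other entries. TPM weights short RNAs, so the lead of mt-Atp8 by TPM need not be a lead by reads. Replication-dependent histone genes, also a family of near-identical copies, had a median of 5.33 TPM (percentile 100, adjusted permutation p = 0.000575). Hist2h2aa2 (122 ± 13.3), Hist1h2bc (58.2 ± 7.93), Hist1h4m (41.7 ± 4.57) and Hist1h2ap (33.7 ± 5.64) were highest, and Hist1h2al and Hist1h2ao had 0 counts, which allows up to 0.598 and 0.270 TPM. Against expressed genes alone the histone list turned to the low side, at percentile 7.48 (adjusted permutation p = 0.232). Cell cycle genes did not stand apart (median of 1.27 TPM, percentile 78.8, adjusted permutation p = 0.608), with Pcna at 72.7 ± 4.86, Mcm6 at 12.04 ± 2.03, Mcm3 at 8.30 ± 1.53 and Cdk1 at 5.79 ± 0.352 TPM, and Cdc20 and Ccnb2 at 0.21 ± 0.111 and 0.2 ± 0.121 TPM. Against expressed genes alone this list lay on the low side too, at percentile 1.71 (adjusted permutation p = 0.065).

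Small structural RNAs took most of the TPM. The 7SL RNA genes Rn7s2 and Rn7s1, the RNA of the signal recognition particle, held 287347 ± 26109 and 285328 ± 26875 TPM (n = 3). The split between these near-identical genes is uncertain, and together they took 57.3% ± 5.30 of TPM but 7.70% ± 2.13 of expected counts. Rn7sk followed at 50439.7 ± 14956, the RNase P RNA Rpph1 at 39634 ± 12701 and Rmrp, annotated as overlapping entries, at 10313 ± 2969 TPM for the higher entry. Gm22513 (982 ± 639.8), Malat1 (534 ± 692), Gm26447 (501 ± 843) and Gm24497 (433 ± 402) also ranked among the highest noncoding genes. The rank of Gm26447 rests on replicate 1, with 1474, 29.6 and 0 TPM in replicates 1, 2 and 3, and Gm24497 had 503, 0 and 794 TPM. Gm26447 had only 78.9, 2.99 and 6 expected counts in replicates 1, 2 and 3. Gm22513 had 489, 230 and 464 and Gm24497 332, 0.01 and 908, against 244068, 35577 and 48001 for Malat1. The rank of Gm22513 above Malat1 by TPM is therefore uncertain. The TPM of Gm26447 thus rests on few reads and does not follow its counts. Of the cytosolic noncoding list, 2900097C17Rik stood at 62.5 ± 4.62 and Zfas1 at 51.1 ± 16.7 TPM, with Snhg1 at 5.76 ± 1.49 and Snhg5 at 2.68 ± 0.930 TPM lowest. Nuclear-encoded protein-coding genes held 88.5% ± 1.18 of expected counts but 29.9% ± 3.79 of TPM, because TPM weights short RNAs. Mitochondrially encoded protein-coding genes held 0.401% ± 0.0835 and pseudogenes 0.474% ± 0.0948 of expected counts.

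Replicate 1 stood apart from the other libraries. Across 10088 genes of at least 1 TPM, Pearson's r of log2(TPM + 1) was 0.951 between replicates 1 and 2, 0.958 between 1 and 3, and 0.985 between 2 and 3. Spearman's rho was 0.951, 0.957 and 0.986. These are correlations across genes, which are not independent replicates. All pairs differed by far more than counting error, with chi-square per degree of freedom of 198, 140.3 and 67.6, so none of these libraries is a copy of another. The common biological coefficient of variation (BCV) was 0.235 and 8954 of 12515 genes (71.5%) varied beyond counting error at an adjusted p of 0.05 (chi-square test, Benjamini-Hochberg). Without replicate 1 the BCV was 0.116 and 5126 of 12697 genes varied.

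Long noncoding RNAs known to stay in the nucleus were among the RNAs that set replicate 1 furthest apart. Malat1 (ENSMUSG00000092341.3, chromosome 19, 5795690 to 5802672) stood at 1333, 118 and 152 TPM in replicates 1, 2 and 3, Xist (ENSMUSG00000086503.4, chromosome X, 103460366 to 103483254) at 32.6, 0.42 and 0.35 TPM and Neat1 at 66.01, 13.9 and 17.6 TPM. Relative to the mean log2 CPM of replicates 2 and 3, replicate 1 was 10.5-fold higher for Malat1, 70.96-fold for Xist and 5.17-fold for Neat1. Firre (3.29, 0.55 and 0.54 TPM), Airn (1.46, 0.68 and 0.64 TPM) and Kcnq1ot1 (0.46, 0.01 and 0.01 TPM) were also highest there, whereas Rn7sk (49198, 36143 and 65978 TPM) and Pvt1 (0.5, 0.56 and 0.38 TPM) were not. Meg3 and Miat had 0 counts, which allows up to 0.0264 and 0.0209 TPM, and Tsix had 1.55 expected counts in replicate 2 and 0 in the others. Whether counting used strand is not given in the sources used here, so antisense genes such as Airn, Kcnq1ot1 and Tsix cannot be told from reads of the opposite strand. The list's median log2 difference in replicate 1 was 2.31, above the -0.23 to 0.38 of the central 95% of matched random lists, with 6 of 8 members higher. All 10 genes with the largest BCV were highest in replicate 1. They were Gm26917 (BCV 1.27), Xist (1.24), A130071D04Rik (1.21), Gm37033 (1.19), Kcnq1ot1 (1.17), Fam196b (1.17), Gm37084 (1.16), 4933423P22Rik (1.16), Vasn (1.15) and Gm29488 (1.14). Long noncoding RNA genes took 1.997%, 0.437% and 0.459% of expected counts in replicates 1, 2 and 3, snoRNA and scaRNA genes 0.0217%, 0.00877% and 0.00861%, and ribosomal RNA genes 0.0438%, 0.00373% and 0.00653%. The long noncoding share includes Gm26917, with 164634, 3338 and 3801 expected counts in replicates 1, 2 and 3. The origin of the Gm26917 reads was not tested, so that share need not be nuclear-retained RNA alone.

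**Figure D2:**
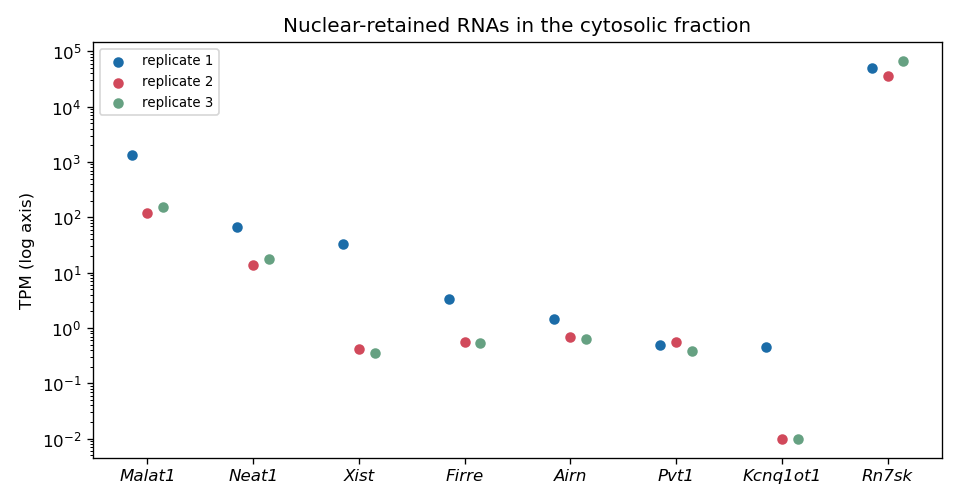
TPM on a log axis of 8 RNAs of the nuclear-retained list, with a point per replicate. Malat1 stands at 1333 TPM in replicate 1 against 118 and 152 TPM in the other libraries, while Rn7sk is highest in replicate 3 at 65978 TPM.

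Antimicrobial, cytokine and interferon-stimulated genes varied between libraries more than random lists of similar level, in every alternative run. The median BCV was 0.316 for antimicrobial and pattern recognition genes, 0.247 for inflammatory cytokines, 0.245 for interferon-stimulated genes, 0.232 for immediate early genes, 0.184 for feedback inhibitors and 0.178 for macrophage identity genes. Nuclear-retained RNAs (0.603), mitochondrially encoded mRNAs (0.193) and ribosomal protein genes (0.154) also lay above matched random lists, giving 9 of 20 lists at adjusted permutation p from 0.00133 to 0.0431. The TLR4 signalling list (0.136) and the NF-kB list (0.141) did not (adjusted permutation p = 0.797 and 0.521). Nor did the AU-rich element (0.140), alternative activation (0.238), cytosolic noncoding (0.237), histone (0.310), cell cycle (0.285), glycolysis (0.165), housekeeping (0.173), neutrophil (0.330) and dendritic cell (0.333) lists. Leaving out each library in turn, 4 of these 9 lists were called every time, namely antimicrobial, cytokine, interferon-stimulated and macrophage identity genes. Their median BCV without replicate 1 was lower, at 0.171, 0.131, 0.112 and 0.105. Without replicate 1 the immediate early (0.115), feedback (0.0954), nuclear-retained (0.166) and mitochondrial (0.0987) lists lost the call. The immediate early and feedback lists lost it without replicates 2 and 3 as well, and the mitochondrial list without replicate 3. The ribosomal protein list lost it without replicate 3 and without replicate 2, where it lay at percentile 2.05 (adjusted permutation p = 0.0915). With the SD of log2(TPM + 1) in place of BCV, the macrophage identity and immediate early lists lost the call (adjusted permutation p = 0.607 and 0.288) and ribosomal protein genes lay below random lists (adjusted permutation p = 0.00114). Calls were gained by cytosolic noncoding RNAs without replicate 1 (adjusted permutation p = 0.032), housekeeping genes without replicate 2 (0.00629) and histones with the SD (0.0085). Matching on gene length as well ended the calls of the immediate early and ribosomal protein lists (adjusted permutation p = 0.059 and 0.0822). Members of a real list can move together, which random lists do not carry. The permutation p-values for spread can therefore be too small, and the calls describe these libraries only.

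Interferon-stimulated genes were highest in replicate 1 and lowest in replicate 2. All 24 members were above the mean of the other libraries in replicate 1, with a median log2 difference of 0.72 against a random range of -0.08 to 0.21, and all were below it in replicate 2 (-0.60). Cxcl10 (ENSMUSG00000034855.13, chromosome 5, 92346638 to 92348889) stood at 851, 185 and 251 TPM in replicates 1, 2 and 3, Rsad2 at 1453, 573 and 644 and Ifit2 at 1486, 656 and 785 TPM. Cytokine genes had a median difference of 0.68 in replicate 1, with 15 of 18 higher. Feedback inhibitors (0.35), antimicrobial genes (0.46), mitochondrially encoded mRNAs (0.46) and NF-kB genes (0.28) were above their random ranges in replicate 1 too. Histone (-0.51), cell cycle (-0.48), glycolysis (-0.26), ribosomal protein (-0.26), housekeeping (-0.14) and macrophage identity (-0.14) lists were below theirs. The immediate early list stayed inside its range in replicate 1 (-0.11). In replicate 3 it lay above its range (0.12 against -0.11 to 0.09), with 19 of 24 members higher. In replicate 2, ribosomal protein (0.30), histone (0.47), glycolysis (0.12) and macrophage identity (0.05) lists were above their ranges, and cytokine (-0.58), antimicrobial (-0.59) and feedback (-0.23) lists below. In replicate 3, neutrophil markers (0.38), alternative activation (0.31) and antimicrobial genes (0.23) were highest above theirs, and nuclear-retained RNAs (-0.96), cytosolic noncoding RNAs (-0.31) and cytokines (-0.24) furthest below. Across 20 lists and 3 libraries, 35 list medians lay outside the central 95% of matched random lists. The number was the same with DESeq2 factors, 31 over 17 lists on protein-coding genes alone and 32 over 18 lists on protein-coding transcripts alone. On those transcripts housekeeping genes in replicate 1 (-0.08), macrophage identity genes in replicate 2 (0.03) and histones in replicate 3 (0.06) lay inside their ranges. Dendritic cell markers lay above theirs in replicate 1 (0.80), and ribosomal protein genes below in replicate 3 (-0.06). On protein-coding genes or transcripts, alternative activation and dendritic cell markers lay below in replicate 2. The differences of the 3 libraries depend on one another, and random lists do not carry the co-expression of real ones, so these positions describe the libraries and carry no p-value.

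**Figure D3:**
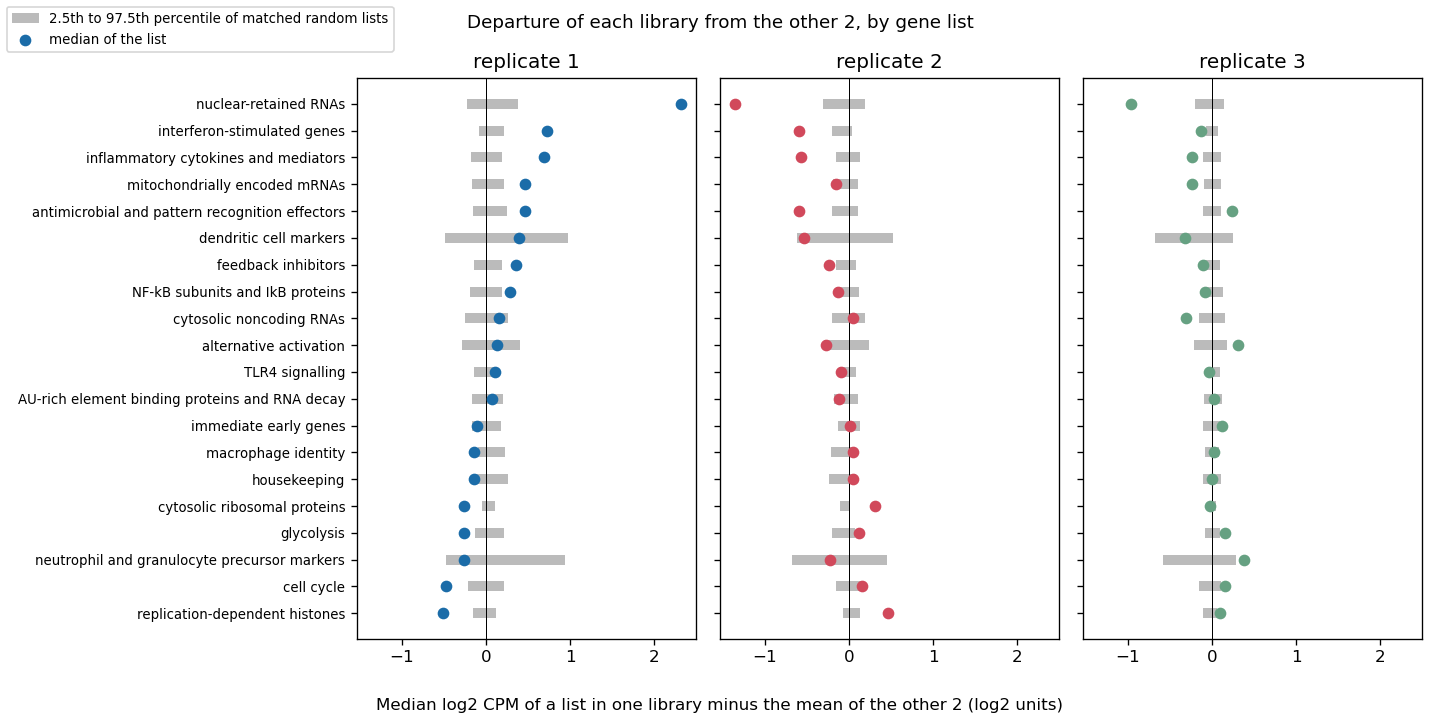
Median log2 CPM of each gene list in one library minus the mean of the other 2, one panel per replicate, with the central 95% of 10000 matched random lists as grey bars. In replicate 1 the nuclear-retained list lies at 2.31 and the interferon-stimulated list at 0.72, and in replicate 2 they lie at -1.35 and -0.60.

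A protein-coding transcript led in each gene examined for isoforms, at unequal shares. Of 18 genes examined, 15 had a leading transcript above 50% of the gene's TPM and 9 one above 90%, and all 18 leading transcripts are annotated as protein coding. The leading transcripts held 100% ± 0 for Tnf and 100% ± 0 for Socs3, 99.4% ± 0.580 for Myd88, 99.3% ± 0.04 for Actb, 99.1% ± 0.392 for Nfkbia and 98.3% ± 0.492 for Irak3 (n = 3). Those of Cxcl2, Rela and Nfkbiz held 95.4% ± 1.87, 94.7% ± 1.82 and 92.9% ± 0.918, and those of Fos, Irak2 and Il1rn 87.6% ± 12.4, 75.9% ± 4.54 and 72.3% ± 0.537. Zfp36 was at 59.7% ± 3.94, and Nfkb2, Irak1 and Nfkb1 at 48.8% ± 7.96, 47.9% ± 4.32 and 45.01% ± 5.08. For Dusp1 the leading share was 50.9%, 79.9% and 83.1% in replicates 1, 2 and 3, and for Tnfaip3 44.1%, 68.3% and 66.9%. The quantification made directly from reads named the same leading transcript for 17 of the 18 genes, with Nfkb2 the exception. The Nfkb2 transcript that leads by mean share held 40% in replicate 1, where Nfkb2-202 held 46.6%. No test was run, since an exact sign-flip test over 3 libraries cannot go below p = 0.25.

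Gene levels correlated closely between the 2 kinds of quantification. The comparison covered the 10088 genes with a mean of at least 1 TPM in the gene table. Genes counted only in the table made from reads were thus left out. Pearson's r of log2(TPM + 1) was 0.963, 0.972 and 0.970 in replicates 1, 2 and 3, and Spearman's rho 0.965, 0.972 and 0.971. The scales of the tables differed. Protein-coding genes took 34.9%, 28.1% and 28.1% of TPM in the gene table but 24.7%, 10.2% and 8.24% in the table made from reads.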

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

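The test of the pattern in the reads-based table was chosen after the result was seen. The phiX control, a bacteriophage genome added to sequencing runs, took 0.435%, 0.134% and 0.0823% of expected counts in replicates 1, 2 and 3.

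In the table made from reads, the processed pseudogenes Gm12895 (chromosome 4, 122455210 to 122455435) and Gm12896 (chromosome 4, 122122847 to 122123072) took 1.31%, 12.4% and 17.2% of estimated counts in replicates 1, 2 and 3, and both had 0 expected counts in the gene table. They are among 7 genes with over 1000 estimated counts in each library and 0 expected counts, which together took 39.8%, 68.7% and 76.95% of TPM in that table. A candidate explanation for the different protein-coding scale of the tables is that reads of repeated sequence were kept by one quantification and dropped by the other. Leaving those genes out turned the gap in every library. Protein-coding genes then took 40.98%, 32.5% and 35.7% of TPM in the table made from reads, above the 34.9%, 28.1% and 28.1% of the gene table. The largest ratio between the tables, in replicate 3, went from 3.41 to 1.27 in the opposite direction. The removal thus more than closed the gap, while the bound set for a full account, 1.2, was not reached. The 7 genes were chosen for having counts in only one table, and they held much of its TPM. Leaving them out had to raise the protein-coding share whatever the cause. The result therefore cannot tell whether repeated sequence explains the gap. The reversed difference was not tested further, and no biological explanation was tested.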

How the results depend on the processing

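The list spread without each replicate and the departures on protein-coding genes or transcripts alone were chosen after seeing the data. Over all alternatives run on the main values and counts, 40 kept the direction or size, 9 moved it and 1 turned it. Those counted as kept include sizeable changes. Lists called above random lists numbered 12 of 23, but 8 of 17 with expressed genes alone. Detected genes numbered 9583, but 7394 with the quantification made from reads and 12387 with at least 10 expected counts. With members of at least 1 TPM, feedback minus cytokine turned to -0.16, since fewer genes enter and low cytokines drop out, and the histone list fell to percentile 7.48. The count of detected genes was 5961 at 5 TPM, and the protein-coding share was 29.9% of TPM, because TPM weights short RNAs. The lowest correlation of libraries was 0.979 with all genes above 0 and 0.924 with a pseudocount of 0.1, which brought the mean correlation of the quantifications to 0.948. Without a filter on low counts, where more genes enter, BCV was 0.456. Leaving out each replicate gave a BCV from 0.116 to 0.274, 5126 to 7667 varying genes (both lowest without replicate 1) and 5 to 7 lists of higher spread. The spread of the ribosomal protein list fell below random lists with the SD of log2(TPM + 1), at 0.127. It was 0.102, 0.155 and 0.191 without replicates 1, 2 and 3, called higher only without replicate 1 and on the low side, without a call, without replicate 2. The cause was not tested for the correlations or the ribosomal list. Of values for single lists, 258 kept their call or their lack of one, 17 lost the call, 3 gained it and 3 called ones turned. Lists without a call changed sides too, among them cell cycle level with expressed genes alone (percentile 1.71). No paired analysis was possible because there is a single group.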

Other observations

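Except for the retained-intron share of protein-coding genes, the tests in this part were chosen after the result was seen, in whole or in part. Both scaling tests replaced earlier ones after results were seen. The earlier nuclear test asked for a median log2 difference above 1, and the list had 2.31. The earlier interferon test took the difference between the interferon and immediate early medians, 0.84 log2 units with all genes and 0.83 on protein-coding transcripts. It lay between its bounds of 0.5 and 1.0 and decided nothing. The excess over random lists that replaced them was known when it was chosen, and exchanging TMM for DESeq2 factors cannot change it. The pattern first included immediate early genes lower in replicate 1, which was dropped because their median of -0.11 lay inside the random range.

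Single genes differed between the libraries. The scavenger receptor Marco was highest in replicate 3, at 67.9, 40.7 and 162 TPM in replicates 1, 2 and 3. Egr1 (0.99, 2.92 and 3 TPM), Nr4a1 (0.19, 0.86 and 0.66 TPM) and Ier2 (2.32, 4.5 and 5.27 TPM) were lowest in replicate 1, where 15 of 24 tested immediate early genes were lower than the mean of the other libraries. Ifnb1, which encodes interferon beta, stood at 4.04, 0.79 and 0.97 TPM and Nos2 at 8.71, 2.16 and 2.73 TPM, both highest in replicate 1 like most cytokine genes. Among the Y-linked genes Ddx3y, Kdm5d, Eif2s3y and Uty, Kdm5d had 1 count in replicate 2 and all other counts were 0, which allows up to 0.0630 TPM for the least certain of them, Eif2s3y.

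Replicate 1 held more nuclear-retained RNA than the other libraries. Nuclear RNA carried into its cytosolic fraction is a candidate explanation. The share of protein-coding gene counts on transcripts annotated as retained intron was 2.76%, 1.35% and 1.28% in replicates 1, 2 and 3, a ratio of 2.10 to the mean of the other libraries, and it was highest in replicate 1 for 1783 of 2119 genes with at least 100 such counts. A scaling factor, by library size or by a few abundant RNAs, moves all genes of a library alike, which the values forbid: the list lay 1.93 log2 units above the central 95% of matched random lists, and ribosomal protein genes (-0.26) lay below theirs. Rn7sk, also nuclear, was not higher in replicate 1, the carry-over was not measured directly, and no biological explanation was tested.

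Interferon-stimulated genes were higher in replicate 1 as well. The values forbid a scaling factor as the whole cause here too, since the list lay 0.50 log2 units or more above the central 95% of matched random lists with all genes, protein-coding genes or protein-coding transcripts. Nuclear RNA stays open as a possible explanation, although the genes kept 1.07 of their difference on protein-coding transcripts alone, past the bound of 0.8 set beforehand against it. That bound was wrong, because exon reads of nuclear RNA fall on those transcripts too, so this explanation cannot be told apart from others; a retained-intron share added afterwards, 2.14 times the mean of the other libraries, is near the 2.10 of all protein-coding genes and does not decide it. A difference between the cultures in their interferon response was not tested, since the labels give none.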
